A study of Mus musculus with 8 samples.

How the data were processed

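RNA of colon epithelial cells from C57BL/6J mice was measured on 8 Affymetrix arrays, 1 array per sample. Wild-type (WT) mice and mice lacking SMS2 (gene symbol Sgms2), an enzyme that makes sphingomyelin from ceramide, were either untreated or given 3.5% dextran sulfate sodium (DSS), a chemical that injures the colon lining, in drinking water for 2 days. Each of the 4 groups held 2 arrays, which the labels call biological replicates, and whether a replicate was 1 mouse or a pool is not given in the sources used here. Total RNA was isolated on columns and turned into labelled single-stranded DNA, per the labels' protocols. The deposited values are on a log2 scale. Affymetrix Expression Console made them, per the submitters' processing notes, and the normalization and background correction it applied are not given in the sources used here. The values were used as deposited, with no further normalization.

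The table held 28846 rows, of which 6640 were control rows and were left out of all tests. Of the other rows, 19572 had 1 gene symbol in the platform annotation, none had several, and 2634 had no symbol. All 19572 matched the mouse assembly GRCm38.p6 by Entrez number, and no symbol had to be updated. The rows gave 19505 distinct genes. For the 55 genes with several rows, the row of highest mean was kept. The lowest 33.3% of genes by mean over all 8 arrays, below a mean of 5.15 on the log2 scale, were left out, and 13003 genes were tested. The files name no genome build, so no coordinates are given, and the assembly was used only for names and for which genes lie next to each other. A set of 39 genes had values identical to another gene, which the array cannot separate.

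The number of arrays limits the precision. Array medians ran from 5.93 to 6.09 on the log2 scale. The 75th percentile of the 5222 negative-control rows, between 6.00 and 6.24 per array, was taken as background. Where every array of 1 group lay under it and the other group did not, the difference is given as a lower bound ("at least N-fold"), from the bright group's mean signal against the mean background of the other group's arrays.

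A linear model with 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, leaving 4 residual degrees of freedom, with empirical Bayes moderation (prior degrees of freedom 7.27). The 7 comparisons were DSS against untreated in each genotype, knockout against WT in each treatment, the difference between the 2 DSS changes (interaction), and the DSS and genotype effects averaged over the other factor. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. P-values measure the spread between these samples. With 2 arrays against 2 an exact permutation test cannot go below p = 0.333, so no such test is given.

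Of 46 gene lists written before the data were examined, 41 had at least 5 tested genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists of B and plasma cells, mast cells and eosinophils, adipocytes, erythroid cells and mitochondrially encoded genes, with 3, 4, 4, 2 and 0 tested genes, were not tested. The lists covered epithelial cell types, other cell types that the preparation could hold, pathways of colitis and lipid metabolism, and genes of the proximal and distal colon. None of the camera calls held when the inter-gene correlation was estimated from the residuals. Genes were named by a rule fixed beforehand: per comparison, the genes past the threshold with no overlap between the groups' arrays, ranked by size of change, up to 12 in each direction for the 4 pairwise comparisons and up to 6 for the others, without predicted genes and with Sgms2, Sgms1 and Samd8 always included. Directions with under 6 such genes were filled up to 6 with genes that did not pass but changed by at least 1 on the log2 scale, and these are said not to pass. Up to 4 members of smallest p were named from each list that passed or held a gene past the threshold, and up to 3 members of highest mean from each list of other cell types.

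The pipeline was tested on 10 simulated data sets per comparison with 200 changed genes among 13003. A change of 1 on the log2 scale was recovered for 41.5% of genes for DSS in WT, 43.7% for DSS in the knockout, 44.7% for genotype without DSS, 39.5% for genotype with DSS, 8.12% for the interaction, 87.4% for DSS averaged and 89.2% for genotype averaged. A change of 2 was recovered for 86.7% in the interaction and for at least 99.0% in the others. Between 5.94% and 7.88% of calls were false, against a nominal 5%. The simulated noise was normal and independent between genes, with the moderated variance of each gene. Differences that many genes of a real array share were not simulated, so these shares do not cover them. Alternatives covered the filter, the choice of rows, 2 scalings between arrays, the variance model, array weights, the arrays in the fit, a replicate block, the thresholds and leaving out each array. An alternative for values on a linear scale did not apply. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.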

Results

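Expression was measured in colon epithelial cells from 4 groups of mice, WT untreated, WT given DSS, SMS2 knockout untreated and SMS2 knockout given DSS, with 2 arrays in each. Replicate arrays correlated with r between 0.981 and 0.992 over the tested genes, and the median difference between them was 0.24 on the log2 scale in untreated WT, 0.30 in WT with DSS, 0.20 in untreated knockout and 0.33 in knockout with DSS. The number of genes that differed by over 1 log2 unit between replicates was 121, 491, 130 and 755 in the same order. Differences below are log2 with their standard error from limma, signals are group means ± SD (n = 2), and adjusted p-values are those of limma.

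Sgms2, the targeted gene (TC0300002959.mm.2), was low in every knockout array. Its signal was 10.78 ± 0.02 in untreated WT and 11.09 ± 0.26 in WT with DSS, against 7.32 ± 0.02 and 6.91 ± 0.62 in the knockout. The difference was -3.46 ± 0.29 without DSS (adjusted p = 0.00137) and -4.18 ± 0.29 with DSS (adjusted p = 3.08e-05), and the knockout signal stayed above the negative controls. The deleted part of the gene is not given in the labels, so the array does not show whether a functional transcript was left. Sgms1, the other sphingomyelin synthase, had a difference of 0.66 ± 0.23 without DSS (adjusted p = 0.481) and 0.03 ± 0.23 with DSS (adjusted p = 0.975). Samd8, which makes a related lipid, had differences of -0.70 ± 0.25 (adjusted p = 0.498) and -0.28 ± 0.25 (adjusted p = 0.741). None of the 36 tested genes of the sphingolipid list, which includes Sgms1 and Samd8, passed between the genotypes in either treatment, against 2 lower genes in each when adjusted over the list alone.

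Of 16 tested Y-linked genes, Eif2s3y, Uty and Kdm5d followed the treatment and not the genotype, and the other 13 did not pass with DSS in either genotype. These 3 lay under the background in all 4 untreated arrays and were bright in all 4 DSS arrays. In WT the differences were at least 33.7-fold, 15.97-fold and 3.16-fold, and in the knockout at least 24.0-fold, 14.1-fold and 2.89-fold. Averaged over genotypes, the X-linked genes Kdm5c, Kdm6a and Eif2s3x, which partly escape X inactivation and were singled out after their values were seen, were lower in the DSS arrays by -0.95 ± 0.18 (adjusted p = 0.00875), -1.11 ± 0.17 (adjusted p = 0.00232) and -0.78 ± 0.18 (adjusted p = 0.0292). Every DSS comparison below therefore also sets arrays with these Y-linked transcripts against arrays without them.

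**Figure D1:**
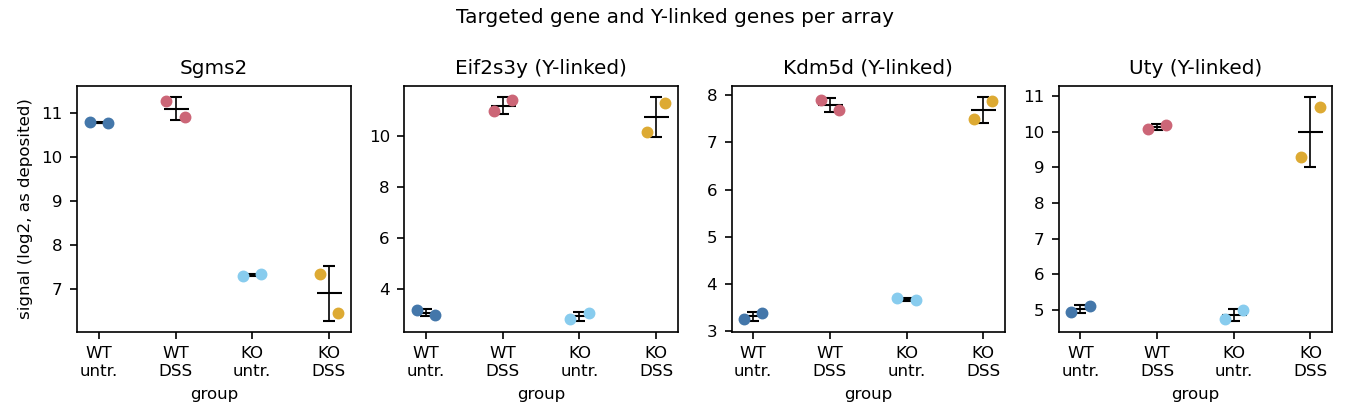
Signal on the log2 scale (y axis) of Sgms2 and 3 Y-linked genes in each array (points, 2 per group on the x axis), with group means and SD as bars. Sgms2 was near 11 in both WT groups and near 7 in both knockout groups, whereas Eif2s3y was about 3 in the untreated arrays and about 11 in the DSS arrays.

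WT mice given DSS had higher levels of many genes of connective tissue and some of vessels and myeloid cells than untreated WT mice. They had lower levels of single genes of steroid and bile acid handling. The matrix genes Dcn, Col3a1, Lum, Dpt and Efemp1 rose by 4.65 ± 0.36, 4.11 ± 0.49, 4.002 ± 0.37, 3.87 ± 0.36 and 3.85 ± 0.40, and the plasma glutathione peroxidase Gpx3 by 3.70 ± 0.30. Ccl21a, a chemokine of lymphatic endothelium, rose by 3.73 ± 0.33, and Ccl21b and Ccl21c, which the array cannot separate, by 3.96 ± 0.34. The steroid dehydrogenases Hsd3b3 and Hsd3b2 fell by 6.33 ± 0.28 and 5.57 ± 0.27, the matricellular gene Ccn3 by 5.60 ± 0.34, the esterase Aadac by 5.37 ± 0.28 and the aldo-keto reductase Akr1c19 by 4.15 ± 0.30. Also lower were the calcium-binding S100g (-3.89 ± 0.66), the bile acid binding Fabp6 (-3.24 ± 0.39), Cyp2d26 (-2.94 ± 0.29), Osr2 (-2.62 ± 0.53) and the bile acid exporter subunit Slc51a (-2.57 ± 0.33). Ceacam12 and Zan fell to background, by at least 7.02-fold and 4.02-fold.

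In the same comparison, 13 of 18 fibroblast and matrix genes rose and none fell (17 when adjusted over the list alone), with Sparc at 3.31. The list was higher by camera (adjusted p = 4.07e-27), with an adjusted p = 0.183 with an estimated correlation. Of 14 endothelial genes 8 rose (10 when adjusted over the list alone), among them Plvap (2.48) and Lyve1 (2.70), with Eng and Cdh5 rising from background by at least 2.89-fold and 4.97-fold. Of 15 macrophage and dendritic cell genes 7 rose (10 when adjusted over the list alone), among them Lyz2 (3.46), Fcgr3 (2.69) and Ly6c2 (2.42). Both lists were higher by camera, with an adjusted p = 0.183 with an estimated correlation. None of 14 smooth muscle genes passed, also when adjusted over the list alone, although all 14 were above the untreated level (adjusted p = 0.00192 by camera and adjusted p = 0.533 with an estimated correlation). Of 28 interferon gamma and antigen presentation genes 9 rose (10 when adjusted over the list alone), with H2-Aa at 3.01, H2-Ab1 at 2.48, H2-Eb1 at 2.23 and the interferon-induced Gbp2 at 2.08. Of 31 NF-kB targets, cytokines and chemokines 7 rose (12 when adjusted over the list alone), including the cyclooxygenase Ptgs2 (2.55), Csf1 (2.51) and Ccl3, the last from background by at least 3.43-fold. Both lists had an adjusted p = 0.183 with an estimated correlation. Among signalling genes Bmp4 rose by 3.42, Sfrp1 by 3.29 and Grem1 from background by at least 6.21-fold, with an adjusted p = 0.408 with an estimated correlation for their list. Of 29 proliferation genes 8 fell (16 when adjusted over the list alone), with Ube2c at -1.88, Bub1b at -1.40 and Plk1 and Ccnb2 at -1.36, and the stem cell genes Lgr5 (-1.90) and Axin2 (-1.42) fell too, with an adjusted p = 0.345 with an estimated correlation for each of these lists. Of 25 colonocyte genes 6 fell and 1 rose (8 and 1 when adjusted over the list alone), such as Tmigd1 (-2.34), Slc9a3 (-2.07) and Slc51b (-1.94), and 4 of 24 xenobiotic and steroid genes fell (8 when adjusted over the list alone), with Ces1g at -1.95 and Ugt2b5 at -1.64. These lists had an adjusted p = 0.374 and 0.183 with an estimated correlation.

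In all, 525 of 13003 genes passed in WT, 379 higher and 146 lower. Transcripts of exocrine pancreas were abundant in 1 of the 2 arrays: Amy2a5 and Cpa1 had signals of 15.17 and 12.55 in WT DSS replicate 1, against 5.55 and 5.04 in replicate 2. The count was 988 when that array and knockout DSS replicate 1, with weaker pancreatic signal, were left out, a choice made after seeing the data. That fit has 1 array in each DSS group and takes its spread from the untreated arrays alone, which varied less. The count was 215 and 245 without WT untreated replicate 1 or 2 and 300 without WT DSS replicate 2. S100g and Osr2 lost their call with trend and robust moderation and with arrays left out. The count was 799 at an adjusted p under 0.1 and 11 with the mean of the fibroblast list as a covariate, also added after seeing the data.

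**Figure D2:**
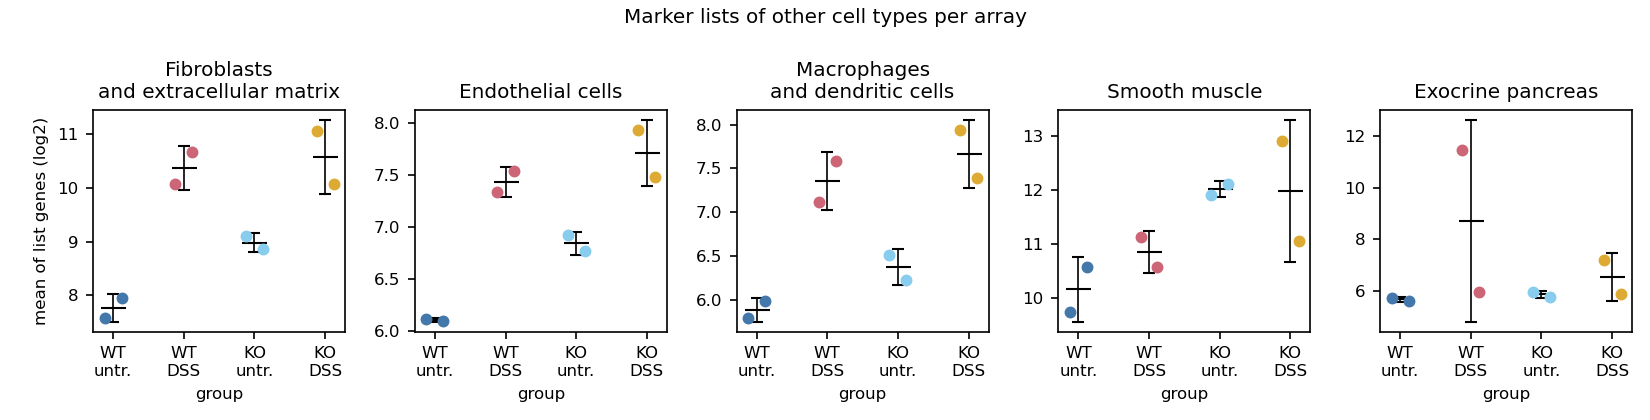
Mean log2 signal (y axis) of 5 marker lists of other cell types in each array (points, 2 per group on the x axis), with group means and SD as bars. The fibroblast list ran from 7.59 and 7.95 in untreated WT to 10.08 and 10.66 in WT with DSS, and the pancreas list stood at 11.45 in WT DSS replicate 1 and 7.19 in knockout DSS replicate 1.

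SMS2 knockout mice given DSS had higher levels of some immune and stromal transcripts, and lower levels of single genes of transport and metabolism, than untreated knockout mice. The B cell chemokine Cxcl13 rose by 3.08 ± 0.28, the immunoglobulin joining chain Jchain by 2.81 ± 0.41, Igfbp5 by 2.69 ± 0.43, the mesenchymal transcription factor Tcf21 by 2.61 ± 0.39, Dpt by 2.46 ± 0.36, the WNT inhibitor Sfrp1 by 2.43 ± 0.33 and Lum by 2.34 ± 0.37. The acute phase gene Serpina3n and the complement gene C1qc rose from background by at least 4.27-fold and 3.04-fold. The sulfate transporter Slc13a1 fell by 3.96 ± 0.35, the neprilysin gene Mme by 3.19 ± 0.47, Slc51a by 2.83 ± 0.33, the bile acid importer Slc10a2 by 2.61 ± 0.24, Tmigd1 by 2.58 ± 0.28, Abca12 by 2.49 ± 0.30, Cyp2d26 by 2.36 ± 0.29 and sucrase-isomaltase (Sis) by 2.34 ± 0.36. S100g (-3.35 ± 0.66, and -2.02 without knockout DSS replicate 1), Cyp4b1 (-2.94 ± 0.47) and Naaladl1 (-2.69 ± 0.40) were lower too, and Cubn fell to background, by at least 3.59-fold.

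Of the fixed lists in the knockout, 7 of 18 fibroblast genes, 5 of 15 macrophage and dendritic cell genes and 3 of 14 endothelial genes rose, against 17, 11 and 8 when adjusted over the list alone. These lists had an adjusted p = 0.239, 0.206 and 0.231 with an estimated correlation. Mgp rose by 1.94, Lyve1 by 2.02 and C1qb from background by at least 2.24-fold. Of 24 xenobiotic genes 5 fell (11 when adjusted over the list alone), with Aldh1a1 at -1.78, Cyp2c65 at -1.50 and Abcg2 at -1.17, and 3 of 25 colonocyte genes fell (9 when adjusted over the list alone), both lists with an adjusted p = 0.206 with an estimated correlation. Axin2 (-1.97) and Lgr5 (-1.84) fell among 16 stem cell genes (adjusted p = 0.454 with an estimated correlation). None of 29 proliferation genes passed, against 3 lower genes when adjusted over the list alone (adjusted p = 0.606 with an estimated correlation). The mean of that list was 8.51 in knockout DSS replicate 1 and 9.34 in replicate 2, against 9.36 and 9.49 in the untreated knockout arrays and 8.65 and 8.45 in the WT DSS arrays. Of 23 ion and water transport genes none passed, against 1 lower gene when adjusted over the list alone (adjusted p = 0.632 with an estimated correlation). Altogether 121 genes passed, 70 higher and 51 lower. The knockout DSS arrays differed most from each other: 48 genes passed without replicate 1 and 297 without replicate 2 of that group, 43 and 18 without untreated knockout replicate 1 or 2, 73 without either untreated WT array, 14 in a fit on these 4 arrays alone, 190 at an adjusted p under 0.1 and 4 with the fibroblast covariate. Those that passed without knockout DSS replicate 1 were 19 higher and 29 lower. Of the single genes named first, Cxcl13, Serpina3n, Slc13a1, Slc10a2 and Tmigd1 passed under every setting chosen beforehand and with each array left out. Slc51a and Cyp2d26 lost their call in the fit on these 4 arrays alone, and each of the others with at least 1 array left out. The exocrine pancreas list had a mean of 7.19 in replicate 1 of the knockout DSS arrays and 5.91 in replicate 2.

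The DSS changes of the 2 genotypes were related across genes (Pearson r = 0.57, Spearman rho = 0.38 over 13003 genes, which are not independent replicates). Of 2004 genes at an unadjusted p under 0.05 in WT, 82.6% had the same sign in the knockout. A total of 94 genes passed in both genotypes in the same direction and none in opposite directions, where 2.61 would be expected of independent lists. The 2 comparisons share no arrays, but they take each gene's spread from the same fit. Both also set arrays with the Y-linked transcripts against arrays without them. The lists are therefore not independent, and their agreement cannot be assigned to DSS alone. Averaged over genotypes, 718 genes passed, 451 higher and 267 lower (392 and 400 with the array medians set equal), with Dcn (3.30 ± 0.26), Col3a1 (3.22 ± 0.35) and Cxcl13 (3.22 ± 0.19) among the highest and S100g (-3.62 ± 0.47), Slc13a1 (-3.08 ± 0.25), Slc51a (-2.70 ± 0.24) and Cyp2d26 (-2.65 ± 0.20) among the lowest. Here 16 of 18 fibroblast, 9 of 14 endothelial and 9 of 15 macrophage genes rose (18, 10 and 13 when adjusted over the list alone), and 10 of 24 xenobiotic, 9 of 25 colonocyte and 9 of 29 proliferation genes fell (13, 11 and 20 when adjusted over the list alone). The lists had an adjusted p = 0.213 with an estimated correlation, and the proliferation list 0.359. The mean of the fibroblast list differed by 2.09 ± 0.30 and that of the smooth muscle list by 0.33 ± 0.53. The count was 401 and 469 without WT untreated replicate 1 or 2, and 472 and 396 without knockout untreated replicate 1 or 2. It was 1087 at an adjusted p under 0.1 and 10 with the fibroblast covariate.

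**Figure D3:**
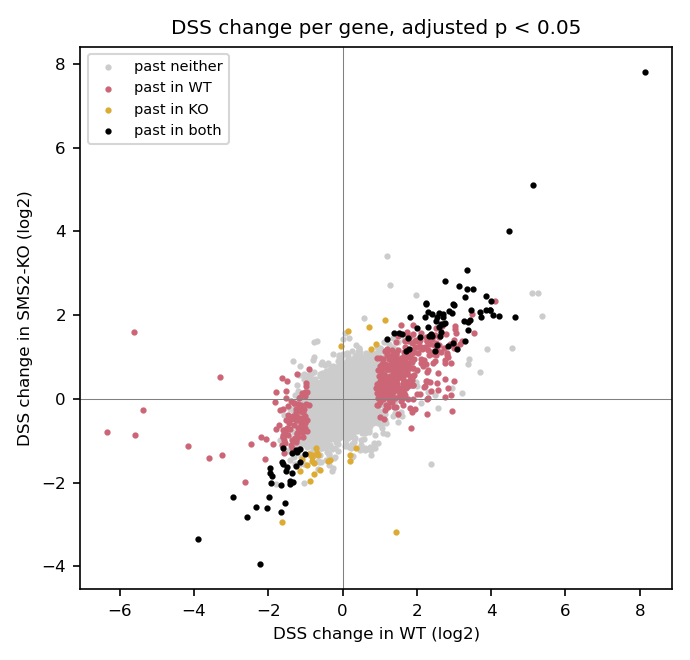
Log2 DSS change of each of 13003 genes in WT (x axis) and in the SMS2 knockout (y axis), with colours for genes past the threshold in neither, 1 or both genotypes. The 94 genes past in both lie in the 2 quadrants of equal sign.

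Without DSS, 44 genes were higher and 7 lower in the knockout, against 1 higher and 2 lower without WT untreated replicate 2 and 3 higher and 4 lower without knockout untreated replicate 1. The peptidase gene Mme was at background in WT and at least 11.5-fold higher in the knockout, with signals of 5.56 ± 0.50 in WT and 9.66 ± 1.28 in the knockout. The metallothionein Mt2 was higher by 2.67 ± 0.41, the clock output gene Dbp by 2.40 ± 0.29, the lipid carrier Apoe by 2.36 ± 0.26, the phosphohydrolase gene Hddc3 by 2.33 ± 0.22 and Zfp605 by 2.11 ± 0.31. Transcripts of mesenchyme and vessels were higher too: Igfbp7 by 2.19 ± 0.30, Dcn by 2.17 ± 0.36, the pericyte gene Rgs5 by 2.17 ± 0.35 and Ccl21b by 2.11 ± 0.34, with Grem1 at least 3.65-fold and the interferon-inducible Ifi211 at least 2.20-fold above background. Besides Sgms2, the glycosyltransferase-like Glt1d1 (at least 3.09-fold, at background in the knockout), Tmem117 (-1.65 ± 0.27), Dnase1l2 (-1.64 ± 0.30), the centromere gene Hjurp (-1.56 ± 0.22), Sstr1 (at least 1.65-fold) and Cdc42bpg (at least 1.72-fold) were lower.

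Smooth muscle genes were all above WT in the untreated knockout, 14 of 14, although Pln alone passed over all genes (from background by at least 2.75-fold) while all 14 passed when adjusted over the list alone. That list, with an adjusted p of 1.23e-21 by camera, had an adjusted p = 0.402 with an estimated correlation. Of 18 fibroblast genes 3 were higher (Sparc 2.08, Dcn 2.17, Vim 1.60), as was Plvap (1.49) of 14 endothelial genes, against 12 and 7 when adjusted over the list alone. These lists also had an adjusted p of 0.402 with an estimated correlation. The smooth muscle list had means of 9.74 and 10.58 in the untreated WT arrays and 11.91 and 12.11 in the untreated knockout arrays. The fibroblast list had means of 7.59 and 7.95 against 9.10 and 8.86. More stroma and muscle taken with the epithelium of the untreated knockout mice cannot be told apart from a change within cells. The water channel Aqp8 was higher by 2.06 and the fatty acid receptor Cd36 from background by at least 1.81-fold. In all 51 genes passed. The count was 7 and 3 without WT untreated replicate 1 or 2, 7 and 24 without knockout untreated replicate 1 or 2, 132 without either knockout DSS array, 241 with array weights, 84 with all rows of the table, 32 after quantile normalization, 78 at an adjusted p under 0.1, 3 with the fibroblast covariate and 252 in a fit on these 4 arrays alone. Of the genes named here, Hddc3, Sgms2 and Glt1d1 passed under every setting chosen beforehand and with each array left out.

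With DSS, several of the largest differences between knockout and WT were in genes that were low in the WT DSS arrays alone. Ccn3 was higher in the knockout by 6.39 ± 0.34, Hsd3b3 by 5.50 ± 0.28, Aadac by 4.67 ± 0.28, Hsd3b2 by 4.62 ± 0.27 and Akr1c19 by 3.53 ± 0.30, and Zan by at least 6.35-fold. Further genes higher in the knockout were Hddc3 (2.38 ± 0.22), Plac9b (2.32 ± 0.42), Zfp605 (1.99 ± 0.31), the tyrosine catabolism enzyme Fah (1.94 ± 0.30), the glutathione transferase Gsta4 (1.80 ± 0.32) and Cyp2d26 (1.74 ± 0.29). Lower were Igsf23 (-3.36 ± 0.32), the posterior homeobox genes Hoxd13 (-3.19 ± 0.56) and Hoxd11 (-2.21 ± 0.37), the lipid droplet gene Hsd17b13 (-2.47 ± 0.24), Arhgap6 (-2.40 ± 0.23), Tifa, an adaptor of NF-kB signalling (-2.39 ± 0.27), and Trib1 (-2.18 ± 0.30). Tifa is among the 100 tested genes nearest to Sgms2. Tmem116, Glt1d1, Xpnpep2 and Acpp were at background in the knockout with DSS and lower than in WT by at least 6.33-fold, 3.91-fold, 2.85-fold and 2.75-fold. Glt1d1 and Xpnpep2 were at background in the untreated knockout as well, and Xpnpep2 also in untreated WT.

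Some inflammatory lists and a list of immediate early and dissociation genes, which tissue handling also raises, were lower in the knockout with DSS by camera. With an estimated correlation their adjusted p-values were 0.487 for the interferon list and the immediate early and dissociation list and 0.540 for the NF-kB list, and few of their genes passed alone. Of 28 interferon gamma and antigen presentation genes 27 were below WT and only Gbp2 passed (-1.59; also 1 when adjusted over the list alone), and of 31 NF-kB targets and chemokines Ccl5 passed (at background in the knockout, lower by at least 2.76-fold; 8 lower genes when adjusted over the list alone). Of 25 immediate early and dissociation genes 23 were below WT and none passed over all genes, against 8 when adjusted over the list alone. The mean of the T cell list was 6.26 and 6.72 in the WT DSS arrays and 6.16 and 5.99 in those of the knockout, with none of its 10 genes past the threshold, 2 lower when adjusted over the list alone and an adjusted p = 0.540 with an estimated correlation. Lists of myeloid cells were not lower. The macrophage and dendritic cell list had means of 7.12 and 7.59 in the WT DSS arrays and 7.94 and 7.39 in the knockout DSS arrays. For the neutrophil list, with 5 tested genes, they were 6.54 and 6.48 against 7.13 and 6.87. All 14 smooth muscle genes and all 12 enteric neuron and glia genes were above WT, none of them past the threshold (0 and 2 when adjusted over the list alone), with an adjusted p = 0.540 and 0.487 with an estimated correlation. A total of 46 genes passed, 15 higher and 31 lower, against 67, 36 higher and 31 lower, without both arrays with pancreatic signal, where 1 array stands against 1 on the spread of the untreated arrays. Without WT DSS replicate 2 the count was also 46, but 9 higher and 37 lower, with 21 genes shared. The count was 24 without either untreated WT array, 215 without knockout DSS replicate 2, 21 with array weights, 70 with trend and robust moderation and 76 at an adjusted p under 0.1. Of the single genes named first, Plac9b, Zfp605, Fah, Gsta4, Cyp2d26, Hoxd13, Hoxd11, Trib1 and Acpp lost their call with at least 1 array left out.

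Interaction tests asked whether DSS changed expression differently in the 2 genotypes, and 10 genes passed, 6 with a more positive and 4 with a more negative change in the knockout. Since the Y-linked transcripts followed the treatment in both genotypes, a genotype difference that depends on sex cannot be told apart from one that depends on DSS. Hsd3b3, Hsd3b2, Aadac, Akr1c19, Ccn3 and Zan fell in WT and had knockout changes of -0.80, -0.86, -0.27, -1.12, 1.59 and 0.53, none past the threshold. Their interaction estimates were 5.53 ± 0.40, 4.71 ± 0.38, 5.10 ± 0.40, 3.03 ± 0.42, 7.19 ± 0.48 and 3.82 ± 0.32, with adjusted p from 1.07e-04 to 0.0262. Arhgap6 and Hsd17b13 rose in WT by 2.84 and 2.75, and the T cell chemokine Ccl5 rose there from background by at least 2.75-fold, and they had knockout changes of 0.25, 0.04 and 0.18. Zan in WT with DSS, Mme in untreated WT, and Ccl5 and Xpnpep2 in the 3 groups other than WT with DSS lay under background, so their interaction estimates rest partly on signals at that level. Mme fell in the knockout, by 3.19, and had a change of 1.43 in WT, from a signal under background (adjusted p = 0.144). Xpnpep2 and Igsf23, with estimates of -2.21 ± 0.35 and -2.84 ± 0.46, did not pass (adjusted p = 0.0563 and 0.0622). At an unadjusted p under 0.05 there were 709 genes. The count was 5 without either untreated WT array or WT DSS replicate 1, 26 (6 more positive, 20 more negative) without WT DSS replicate 2, 18 without knockout DSS replicate 2, 16 at an adjusted p under 0.1 and 36 (10 more positive, 26 more negative) without both arrays with pancreatic signal, on 1 array per DSS group and the spread of the untreated arrays. The 5 left without either untreated WT array or WT DSS replicate 1 were Hsd3b3, Hsd3b2, Aadac, Ccn3 and Zan, which passed under every setting chosen beforehand and with each array left out. Of the others, Akr1c19, Mme and Ccl5 also lost their call after quantile normalization, Mme with array weights and without either knockout DSS array. Akr1c19, Hsd17b13 and Arhgap6 lost theirs without knockout untreated replicate 2, and Akr1c19 without knockout DSS replicate 1. That of Ccl5 was lost with the array medians set equal, with the replicate block and whichever single array was left out.

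**Figure D4:**
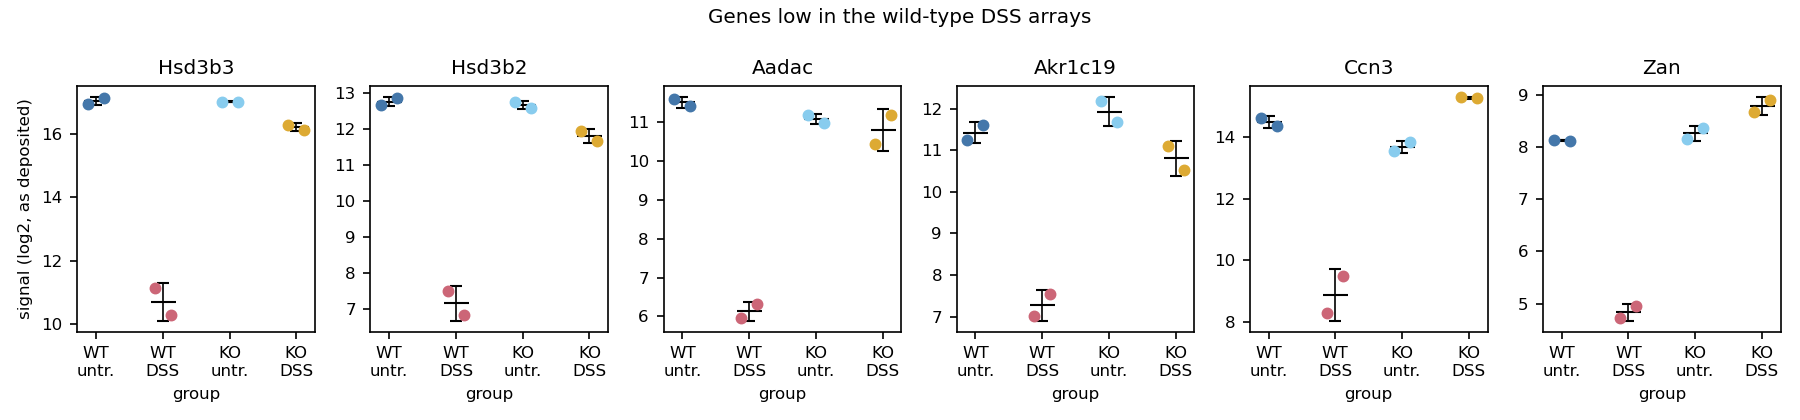
Signal on the log2 scale (y axis) of the 6 genes with a more positive DSS change in the knockout, in each array (points, 2 per group on the x axis), with group means and SD as bars. Both WT DSS arrays lie below the other 6 arrays for each gene, for Hsd3b3 at 11.13 and 10.29 against 16.12 or more.

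Genotype differences present in both treatments were few. Sgms2 and Glt1d1 were lower and Hddc3, Zfp605 and Serpina1a, an alpha-1-antitrypsin gene, were higher in the knockout with and without DSS. These are 5 genes where 0.07 would be expected of independent lists, although both lists take each gene's spread from the same fit. Hddc3 differed by 2.33 without and 2.38 with DSS, and Serpina1a by 1.36 and 1.42. Across 13003 genes the 2 genotype differences, which share no arrays, had r = 0.28 and rho = 0.21. Averaged over treatments, 88 genes passed, 55 higher and 33 lower. A gene can pass in this average through a difference in 1 treatment, and 47 of the 88 had no overlap between the arrays of the genotypes. Among those without overlap, Mt2 (2.10 ± 0.29), Adamts15 (1.80 ± 0.29) and Fah (1.74 ± 0.22) were higher. Acpp (-1.78 ± 0.33), Tifa (-1.72 ± 0.19), Dctd (-1.67 ± 0.26) and Mtmr7 (-1.64 ± 0.26) were lower. Adamts15 in untreated WT and Acpp in the knockout with DSS lay under background, and both, with Dctd and Mtmr7, lost their call with at least 1 array left out. Of 36 sphingolipid genes the ceramidases Asah1 (-1.25) and Asah2 (-1.10) passed here, both lower in the knockout, and the same 2 counts held when adjusted over the list alone. The count was 28 without either untreated WT array, 56 (26 higher, 30 lower) and 47 without untreated knockout replicate 1 or 2, 78 (30 higher, 48 lower) without WT DSS replicate 2, 362 without knockout DSS replicate 2, 185 without both arrays with pancreatic signal (1 array per DSS group, spread of the untreated arrays), 195 at an adjusted p under 0.1 and 10 with the fibroblast covariate.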

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

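The tests of sex, of epithelial share, of swapped labels, of pancreatic tissue and of colon stretch were chosen after the result was seen. The splits of the arrays and both tests of strain DNA were set before.

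The DSS change differed between the genotypes for 10 genes, and that difference is what marks them: Ccn3 (interaction 7.19), Hsd3b3 (5.53), Aadac (5.10), Hsd3b2 (4.71), Zan (3.82), Akr1c19 (3.03), Mme (-4.62), Hsd17b13 (-2.71), Arhgap6 (-2.60) and Ccl5 (-2.20). Zan, Mme and Ccl5 lay under background in at least 1 group. Outside the genes tested, 46 of 1570 rows without a gene symbol were higher in the DSS arrays and 20 lower, averaged over genotypes.

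Hsd3b3, Hsd3b2, Aadac, Akr1c19, Ccn3 and Zan were low in both WT DSS arrays and in no other array. Swapped genotype labels would need Sgms2 to be low in those arrays, and it lay 3.55 log2 units above the highest knockout array. Pancreatic tissue in WT DSS replicate 1 would leave replicate 2 at the level of the other groups, and the same 6 genes were called when chosen without replicate 2, in which their mean lay 4.71 log2 units under the lowest of the other 6 arrays. Another stretch of colon in the wild-type DSS arrays stays open, since the fixed distal list did not decide (adjusted p = 0.0852 by camera) and the proximal list had an adjusted p of 0.916. A genotype-dependent response to DSS, the biological explanation, stays open too. So do a genotype difference that depends on sex, which followed the treatment, and any other difference between the mice. Hoxd13 and Hoxd11 were lower in the knockout than in WT with DSS (-3.19 ± 0.56 and -2.21 ± 0.37). Array weights or a left-out WT array ended both calls. Quantile normalization or trend and robust moderation also ended that of Hoxd13, and a left-out knockout DSS replicate 1 that of Hoxd11. In these settings the differences were -3.01 to -3.37 (SE 0.55 to 0.72) and -1.73 to -2.50 (SE 0.38 to 0.44). Hoxd13 stood at 7.78 and 10.17 in the knockout DSS arrays, and its difference was -1.99 without replicate 1 and -4.38 without replicate 2 of that group.

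Of 18 fibroblast, 14 endothelial and 15 macrophage genes 13, 8 and 7 rose with DSS in WT and 7, 3 and 5 in the knockout (17, 10 and 10, and 17, 8 and 11, when adjusted over the list alone), with an adjusted p of 0.183 in WT and 0.206 to 0.239 in the knockout with an estimated correlation. The fibroblast list started higher in the untreated knockout arrays, at 9.10 and 8.86 against 7.59 and 7.95 in untreated WT. With DSS it stood at 11.05 and 10.08 in the knockout and 10.08 and 10.66 in WT. The smaller knockout counts thus do not show lower levels of these genes with DSS. A lower epithelial share that raises every other cell type alike would raise the lists equally. The fibroblast list rose by 1.76 ± 0.39 log2 units more than the smooth muscle list, 4.49 standard errors. These 2 lists were picked after their changes were seen, and the smooth muscle list stood at 12.90 and 11.05 in the knockout DSS arrays. The values show an unequal rise of these 2 lists and cannot decide on a lower epithelial share. Grouping by chance is argued against: 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes, with 498 genes for the real split and 6 for the highest other in a model of 2 groups. The sex of the animals cannot be told apart from DSS, since the mean of the 16 tested Y-linked genes was 1.14 log2 units higher in the lowest DSS array than in the highest untreated array, with Eif2s3y, Uty and Kdm5d alone past the threshold. DSS itself, sex, a lower epithelial share, and a change in how much stroma was taken with the epithelium stay open.

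Genotype differences were seen with and without DSS. Strain DNA beside Sgms2 acting on the genes next to it would, as the main explanation, put most called genes there. The called genes here are those past the threshold for genotype averaged over treatments. Of the 87 other than Sgms2, 2.30%, Tifa and Emcn, were among its 100 nearest of 13003 tested genes in GRCm38.p6 (Fisher's exact test, two-sided p = 0.144). Only 47 of the 88 called genes had no overlap between the arrays of the genotypes, so the set can hold differences of 1 treatment. The share argues against this explanation for most genes called in the average, and an effect on Tifa or Emcn alone stays open. Strain DNA in other stretches of the genome is left open, with 10 called genes that had a called neighbour within 5 tested genes, against a median of 4 in 10000 random sets (permutation p = 0.0990). The splits are too few for a share under 0.05 once that by DSS, a structure of the samples, is counted: 2 of the 35 splits gave as many genes as the real one, which called 6 in a model of 2 groups, the other being that by DSS with 498, and the highest of the rest called 1. In the model of 4 groups 5 genes, Sgms2 among them, passed with and without DSS in the same direction, where 0.07 would be expected of independent lists. Both lists take each gene's spread from the same fit, so they are not fully independent. A difference between the genotypes in how much stroma and muscle was taken with the epithelium stays open too.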

How the results depend on the processing

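The 2 choices on pancreatic arrays and on the fibroblast covariate were made after seeing the data; all others were set before the data were examined. Sgms2 stayed past the threshold with the same direction in both genotype comparisons under every setting chosen beforehand and with each array left out. Comparisons are given in the order DSS in WT, DSS in the knockout, genotype without DSS, genotype with DSS, interaction, DSS averaged, genotype averaged, with counts of 525, 121, 51, 46, 10, 718 and 88 genes.

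At an adjusted p under 0.1 the counts were 799, 190, 78, 76, 16, 1087 and 195. At an unadjusted p under 0.05 with a 2-fold change they were 357, 305, 286, 398, 440 and 176 from the second comparison on. Genotype without DSS gave 84 with all non-control rows, 32 after quantile normalization, 241 with array weights and 252 on its own 4 arrays, where DSS in the knockout gave 14. Genotype with DSS gave 70 with trend and robust moderation and 21 with array weights. Setting the array medians equal turned the split of DSS averaged from 451 higher and 267 lower to 392 and 400. With the replicate block the counts were 474, 102, 48, 45, 10, 699 and 94. Replicate deviations correlated between -0.25 and 0.28 across groups. Each group gives only 1 such deviation per gene, so these values cannot decide whether the replicate numbers pair the samples. Without the pancreatic arrays the counts were 988 for DSS in WT, 252 for genotype without DSS, 36 for the interaction and 185 for genotype averaged. That fit has 1 array in each DSS group and the spread of the untreated arrays alone, so it says nothing about pancreatic tissue. The 252 is the count on the 4 untreated arrays. With the mean of the fibroblast list as covariate the counts were 11, 4, 3, 55 and 15 in the first 5 comparisons and 10 in both averaged ones. The 4 groups, genotype included, account for 93.0% of the variance of that mean. The covariate thus overlaps with the groups compared, and these counts cannot separate the 2.

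Leaving out 1 array, the lone array being assumed to vary like the other groups, gave 215 to 716, 18 to 297, 3 to 132, 24 to 215, 5 to 26, 396 to 1054 and 28 to 362 genes. The lists past the threshold by camera numbered 22, 17, 8, 18, 16, 17 and 13, and 0 in each comparison with an estimated correlation. Fry in one direction gave 9, 2, 0, 0, 0, 10 and 0. In either direction it gave 29 for DSS in WT, 16 for DSS in the knockout, 3 for genotype without DSS, 17 for genotype with DSS, 3 for the interaction and 29 for DSS averaged. Leaving out 1 array gave 11 to 20 lists for DSS in the knockout and 7 to 21 for the interaction. The correlation of DSS changes between genotypes was 0.508 with no filter, 0.693 over genes at an unadjusted p under 0.05 in either genotype and 0.474 to 0.565 with 1 array left out. That of genotype differences was 0.406 over such genes and 0.154 to 0.307. Of values that did not pass, Sgms1 changed sign for DSS in WT without WT DSS replicate 1 (-0.0618, and 0.32 without replicate 2) and for genotype with DSS without WT DSS replicate 2 (-0.16) or knockout DSS replicate 2 (-0.0369), with up to 0.23 without WT DSS replicate 1. Samd8 changed sign for genotype with DSS without knockout DSS replicate 2 (0.0202), with -0.57 without replicate 1. Sgms2 changed sign for DSS in the knockout (0.0290) and DSS averaged (0.17) without knockout DSS replicate 2, with -0.85 and -0.27 without replicate 1, and for DSS averaged without WT DSS replicate 2 (0.0448). Other thresholds change the counts by construction, and for the rest the cause was not tested. With 2 arrays per group and positive controls separated from negative ones with an area under the curve of 0.862 to 0.884, changes near background are given as bounds.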

Other observations

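Further single genes passed with DSS, averaged over genotypes. The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc, of a pore-forming family, rose by 1.20, 1.15 and 0.89, and the acute phase gene Lbp by 1.70. Among hormone genes of enteroendocrine cells Sct fell by 1.29 and Scg2 and Pyy rose by 1.20 and 0.77. Of PPAR and fatty acid oxidation genes Ppara and Pdk4 fell by 1.29 and 1.15. The junction gene Jam2 rose by 1.74. None of these lists except the PPAR list was past the camera threshold (adjusted p = 0.00488), which had an adjusted p = 0.421 with an estimated correlation.

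Among clock genes, averaged over treatments, Dbp was higher (1.61) and Arntl lower (-1.03) in the knockout. The hours at which the mice were taken are not given in the sources used here. Jchain of plasma cells had signals of 14.61 and 15.42 in the WT DSS arrays and 15.61 and 15.15 in the knockout DSS arrays, against 11.76, 12.76, 13.06 and 12.09 in the untreated arrays. Derl3 and Fcer2a, the other tested genes of the B and plasma cell list, did not pass with DSS averaged over genotypes. They differed by 0.33 ± 0.16 and -0.03 ± 0.16 (adjusted p = 0.322 and 0.952 by limma), and Derl3 lay under background in every array. The mean of the neutrophil list, with 5 of 18 genes tested, differed with DSS by -0.21 ± 0.13. Its brightest gene, Cd177, was also on the proximal colon list, and Wfdc21 lay under background, so this mean cannot decide on neutrophils.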
